A study of Mus musculus with 16 samples.

How the data were processed

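RNA was sequenced from iBMDM cells, an immortalised line of mouse bone-marrow-derived macrophages, which the labels name iBMDM MyD88-AGF. Per the labels' protocols, cells were given lipopolysaccharide (LPS, a bacterial cell-wall glycolipid sensed by the receptor TLR4) at 10 ng/mL for 6 h, or left untreated, and passed through a cell sorter. Side scatter, the light that a cell's internal structures deflect, set 2 gates: LPS-treated cells with high side scatter were called responders and those with low side scatter bystanders. An ungated LPS-treated sample, called the LPS pool here, and the untreated sample went through the sorter without a scatter gate. The ungated LPS-treated cells were collected later than the gated ones, so collection order goes with the gate in comparisons with the pool. Cells were lysed in TRIzol LS, the RNA was treated with DNase, and the RNA integrity numbers were above 7.1, per the labels. The libraries were made and sequenced by a service provider. There were 4 groups of 4 replicates, 16 libraries in all. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

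The authors deposited 1 table of raw read counts per gene for all 16 libraries. Per the submitters' processing notes, cutadapt 3.7, fastp 1.1.0, HISAT2 2.2.2 and featureCounts 2.1.1 were used with the GRCm38 (mm10) mouse genome. The strandedness of the library kit, the gene annotation and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies (Ifit3 and Ifit3b, Tgtp1 and Tgtp2, the clustered histone gene H2ac24, Fth1 and Gapdh) are therefore uncertain. So are related genes of similar sequence (H2-K1 and H2-D1) and overlapping or antisense genes. The table holds 27179 Entrez gene identifiers. Of these, 25275 were matched to symbols and coordinates through the RefSeq gene table of GRCm38.p6, the same build. The other 1904 held 0.399% of the counts and stayed in the tests under their number. There were 3 empty columns and 0 columns of other samples. Total counts ran from 15287344 to 25193162 per library.

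Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, library sizes were scaled by the trimmed mean of M-values (TMM), and a quasi-likelihood model with robust spread was fitted to all 16 libraries together, with 1 mean per group and no covariate. The filter left 12589 genes. Tests were two-sided quasi-likelihood F tests with Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 counted as a change. Unless another test is named, every adjusted p of a gene comes from this test. Levels are edgeR CPM values, counts as a rate of the TMM-scaled library total, given as mean ± SD over 4 libraries, and fold changes are from the fit. The contrasts were responder against bystander, LPS pool against untreated, responder and bystander each against untreated and against the LPS pool, and the mean of both sorted groups against the LPS pool. Genes changed at least 2-fold in the LPS pool against untreated made the LPS-induced and LPS-repressed sets, which were then looked up in responder against bystander, a comparison that shares no library with the one that defined them.

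A total of 28 gene lists, for pathways and for markers of other cell types, was written before the data were examined, as were the comparisons, the named-gene rule and most alternatives. Lists were tested with camera (limma 3.58.1) on voom log2 CPM at its preset inter-gene correlation, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Named genes follow a fixed rule: the 12 highest and 12 lowest folds for responder against bystander, the 10 highest and 10 lowest for LPS pool against untreated and the 5 highest and 5 lowest for the mean of the sorted groups against the pool, each with a mean of at least 5 CPM and no overlap between the libraries compared. The rule adds 2 members per list with the smallest p for responder against bystander and at least 1 CPM, and 15 fixed genes of the LPS response. Genes outside it are said to have been chosen after their values were seen, and some genes that the rule names are not reported here.

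The fit was tested on simulated counts, with 200 genes changed in responders by known amounts, in equal numbers up and down. Every library was drawn from the mean levels of the bystander libraries at its own size. For responder against bystander, over 12589 genes, 58% of 100 genes changed by 0.25 on the log2 scale and 93% of 100 changed by 1 were recovered, and 6.21% of the calls were false. In the real comparison 70% of the genes were called, so these rates may not hold for it. The median biological coefficient of variation was 0.0344. Replicates were compared pairwise: the 24 pairs gave chi-square values of 1.62 to 3.13 per degree of freedom, so no pair agreed within sampling noise and none looked like 1 library deposited under 2 names. Same-numbered libraries deviated together from their group means in all 4 pairs of LPS pool with bystander libraries (correlations of 0.391 to 0.475). The same held for responder with untreated libraries (0.169 to 0.605). In the other 4 combinations of groups only the pairs of replicate 2 did (0.240 to 0.288). These correlations followed the neural transcripts described below, so they do not show whether same-numbered samples belong together. For genes with few reads, counts are given; folds and intervals cover counting error and the spread between libraries only, and reads without molecular identifiers are not independent molecules.

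Alternatives were the DESeq2 1.42.0 Wald test with its size factors, RLE and upper-quartile factors, library totals alone, no low-count filter, a stricter filter, only the compared groups in the fit, a replicate block, removal of the genes with most counts, and leaving out each replicate. While the data were examined, a set of 15 neural genes was found at 34.5 to 51.6 CPM in 6 libraries (LPS pool replicates 3 and 4, bystander replicates 3 and 4, responder replicate 1 and untreated replicate 1) and at 0.84 to 2.47 CPM in the other 10. Fits of the 10 libraries without these transcripts, of the 6 with them, and with this set as a covariate were therefore added after the data were seen, as were fits with a replicate block of LPS pool with bystander and of responder with untreated libraries alone. Each group has libraries of both kinds.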

Results

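Gene expression was measured by RNA sequencing in a line of immortalised mouse macrophages after 6 h of LPS at 10 ng/mL, in cells sorted by side scatter into responders and bystanders, in the ungated LPS pool and in untreated cells. Each of the 4 groups had 4 libraries, with totals of 15287344 to 25193162 counts. The series title asks what mediates assembly of the myddosome, the complex that the adaptor MyD88 forms with IRAK kinases after a Toll-like receptor is engaged. The first 3 principal components held 60.2%, 20% and 7.6% of the variance. All 15 genes fixed in advance, from Tlr4 and Myd88 to Il1b, Nos2 and Cxcl10, passed the low-count filter.

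Responders held far more inflammatory transcripts than bystanders of the same LPS treatment. Il1b (chromosome 2, 129364569 to 129371164), which encodes the cytokine interleukin-1 beta, stood at 3265 ± 76.9 CPM in responders and 36.5 ± 32.5 CPM in bystanders (SD, n = 4 each), an 80.9-fold difference with adjusted p = 1.36e-09 in edgeR's quasi-likelihood test. Il1a was 86.8-fold higher, Csf3, the granulocyte growth factor gene, 79.7-fold, Il6 55.7-fold, Nos2, which encodes inducible nitric oxide synthase, 59.9-fold, and the chemokine gene Ccl5 54.9-fold higher. Tnf (chromosome 17, 35199367 to 35202007) was 11.7-fold higher at 2219 ± 25.4 against 189 ± 17.9 CPM, with adjusted p = 1.77e-16. In the other direction, Tlr4 (chromosome 4, 66827551 to 66846581), the LPS receptor gene, was 4.08-fold lower in responders, at 30.7 ± 1.09 against 126 ± 1.49 CPM, with adjusted p = 1.46e-49 by edgeR.

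The folds of the cytokine genes differed between libraries of the bystander group. Bystander replicates 3 and 4 held Il1b at 64.1 and 65.1 CPM and replicates 1 and 2 at 7.79 and 9.03 CPM, beside 6.43 to 9.05 CPM in untreated libraries. The same 2 libraries are among the 6 with neural transcripts, so the 10 libraries without these were also fitted alone. In them the responder-to-bystander fold was 394 for Il1b, 430.2 for Il1a, 527 for Csf3, 374 for Lcn2, 151 for Ccl5, 134 for Il6, 132 for Nos2 and 124 for Saa3. Over all 16 libraries the folds of Lcn2, the lipocalin-2 gene, and Saa3, an acute-phase gene, were 76.7 and 51.8. In the 6 libraries with neural transcripts, Il1b was 49.2-fold, Csf3 48.7-fold and Nos2 43.2-fold higher. Tnf, at 12.9-fold without and 10.9-fold with these transcripts, moved little.

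Some of these genes were close to absent from bystanders. Il1f6 had 0, 1, 19 and 11 reads in the 4 bystander libraries and 749 to 803 in each responder library, and Csf2 had 1, 0, 7 and 6 against 216 to 249. Ccl17 had 1, 3, 24 and 18 against 644 to 693, and Tnfrsf8 1, 0, 12 and 12 against 319 to 392. Il12b, a subunit gene of interleukin-12, had 1, 0, 1 and 0 reads in bystanders and 10, 26, 24 and 13 in responders. Ifnb1, the interferon-beta gene, had 0, 1, 6 and 0 against 16, 18, 27 and 21. All 6 differences passed edgeR's test, at adjusted p = 2.38e-17 for Il1f6, 5.33e-32 for Csf2, 6.66e-26 for Ccl17, 5.22e-19 for Tnfrsf8, 4.39e-10 for Il12b and 1.75e-08 for Ifnb1. Their folds are not given, since they rest on few reads.

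**Figure D1:**
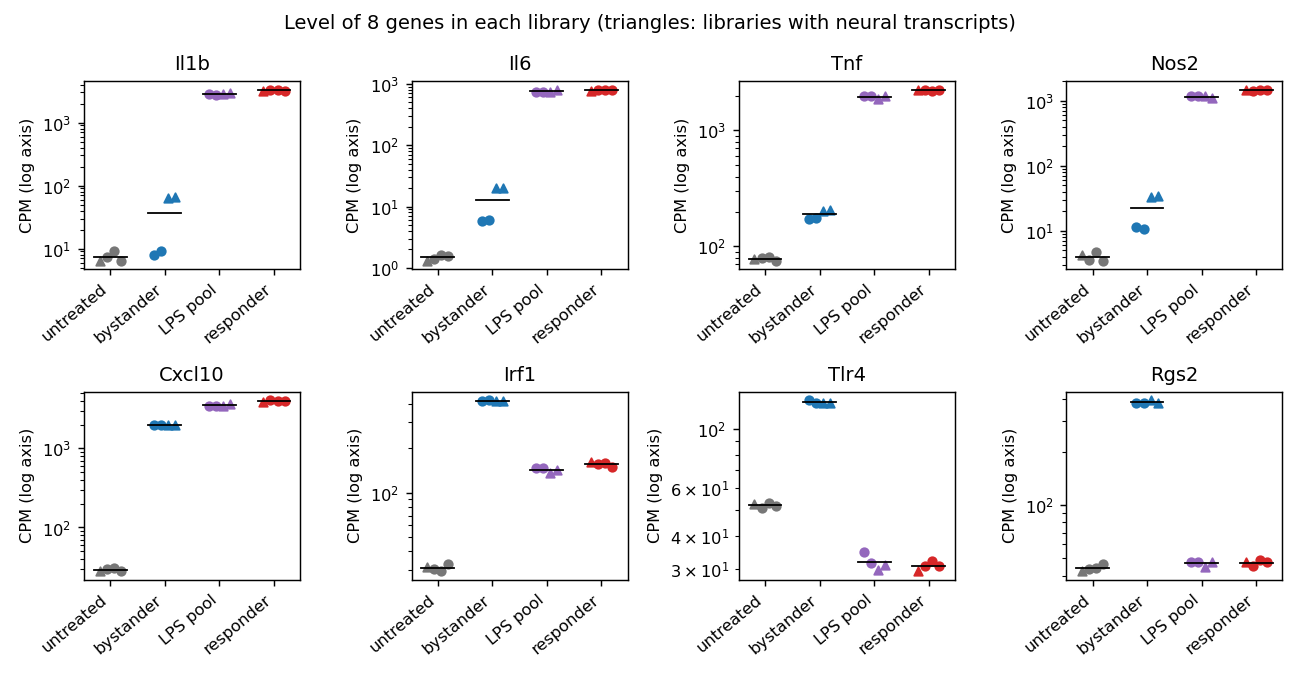
Level of 8 genes in each of the 16 libraries, in CPM on a log axis, by group; points are libraries, black lines group means, and triangles the 6 libraries with neural transcripts. Il1b, Il6, Tnf and Nos2 are higher in responders and the LPS pool than in bystanders, Tlr4, Irf1 and Rgs2 are highest in bystanders, and bystander replicates 3 and 4 lie above replicates 1 and 2 for Il1b.

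By list, the inflammatory genes moved almost as a block between the gates. Of 28 inflammatory cytokines and chemokines tested, 27 were higher in responders and 1 lower, with 23 at least 2-fold higher (camera adjusted p = 2.45e-15). Of 23 NF-kappaB feedback regulators, 22 were higher (camera adjusted p = 4.53e-17), among them Nfkbia, the NF-kappaB inhibitor gene, at 6.62-fold, Tnfaip3 at 5.63-fold, Tnip1 at 6.44-fold and Nfkbiz at 6.10-fold. Of 26 macrophage effector and acute-phase genes, 24 were higher (camera adjusted p = 4.53e-17), including Clec4e at 6.31-fold and Acod1, whose enzyme makes itaconate, at 7.06-fold. Antigen presentation genes were higher for 15 and lower for 2 of 19 (camera adjusted p = 4.63e-07), although H2-K1 and H2-D1, related genes of similar sequence, may share reads. Counts adjusted over the list alone were the same for these 4 lists. All 4 calls held with an estimated correlation, at adjusted p = 0.00902, 0.00132, 0.0105 and 0.00706 in that order.

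Stress and structural genes also differed. Of 17 heat shock genes 16 were higher in responders (camera adjusted p = 4.53e-08), with Hspa8, a constitutive chaperone gene, at 5101 ± 48.1 against 2868 ± 11 CPM. NRF2 targets were higher for 13 and lower for 3 of 18 (adjusted p = 2.02e-05), with Hmox1, the heme oxygenase gene, 2.91-fold higher. Actin cytoskeleton and adhesion genes were higher for 23 and lower for 6 of 30 (adjusted p = 6.51e-07), with Itga5, an integrin subunit gene, 3.91-fold and Actb 1.89-fold higher. With an estimated correlation these lists kept adjusted p = 0.000628, 0.00395 and 0.00295. The unfolded protein and integrated stress response list was higher for 14 and lower for 5 of 23 at adjusted p = 0.0431, and adjusted p = 0.117 with an estimated correlation. The call was also lost with library totals alone (0.373), where its median turned from 0.15 to -0.04, and in the 6 libraries with neural transcripts (0.0607). Ribosomal protein genes were higher for 30 of 32 by a median of 0.14 on the log2 scale (adjusted p = 1.76e-06, and 0.0299 with an estimated correlation), but with library totals alone the median was -0.05 and the call was lost at adjusted p = 0.823. Ribosome biogenesis genes were higher for 17 and lower for 4 of 24 (adjusted p = 0.00409, and 0.0130 with an estimated correlation), a call lost with library totals alone at adjusted p = 0.171.

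Transcripts of dividing cells were lower in responders. All 28 G2/M and mitosis genes were lower, by a median of -0.67 on the log2 scale (camera adjusted p = 1.50e-13), with Kif11, a spindle motor gene, at 34.9 ± 1.91 against 79.0 ± 0.82 CPM and Top2a at 183 ± 4.95 against 307 ± 6.63 CPM. Of 28 G1/S and DNA replication genes 20 were lower and 2 higher (adjusted p = 0.000194), including Pcna at 359 ± 2.67 against 514 ± 9.95 CPM. Cholesterol synthesis and uptake genes were lower for 16 and higher for 2 of 21, and for 3 higher when adjusted over the list alone (adjusted p = 0.00119). With an estimated correlation these lists had adjusted p = 0.000184, 0.0196 and 0.00902. Mitochondrially encoded genes were lower for 6 and higher for 1 of 13 at adjusted p = 0.0423, and adjusted p = 0.169 with an estimated correlation. That call was also lost without responder replicate 1, at adjusted p = 0.0511. The share of all counts from 13 mitochondrially encoded genes was 1.44 ± 0.026% in responders and 1.87 ± 0.0358% in bystanders, with no overlap between libraries, beside 1.45 ± 0.0127% in the LPS pool and 1.97 ± 0.0093% in untreated cells.

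Interferon-stimulated genes did not follow the cytokines. Of 46 tested, 26 were higher and 18 lower in responders, and the list did not differ from other genes (camera adjusted p = 0.152), while with library totals alone 22 were higher and 22 lower and the median turned from 0.17 to -0.02 on the log2 scale. Cxcl10, an interferon-induced chemokine gene, was 2.01-fold higher in responders at 3966 ± 81.8 against 1974 ± 18.3 CPM, and Gbp5, a guanylate-binding protein gene, 3.21-fold higher. Rsad2, the viperin gene, stood at 5554 ± 106 in responders and 6089 ± 29.5 CPM in bystanders. Irf1, a transcription factor gene of the interferon response, was lower, at 157 ± 4.62 against 420 ± 2.54 CPM, as was Iigp1, at 47.3 ± 2.19 against 227 ± 4.58 CPM. Rsad2 and Iigp1 were chosen after their values were seen.

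Genes most strongly lower in responders included Rgs2, a regulator of G-protein signalling, at 47.3 ± 1.67 against 383 ± 6.35 CPM, and Socs1, which encodes a suppressor of cytokine signalling, at 13.2 ± 0.46 against 80.2 ± 3.45 CPM. Cytip stood at 1.42 ± 0.43 against 14.9 ± 0.89 CPM. Others by the rule, Tcp11l2, St6gal1, Otud1, Treml1, Il18rap, Tmem158, Enc1 and H2ac24, were lower by -2.90 to -2.41 on the log2 scale, H2ac24 being a histone gene with near-identical copies. Of 29 TLR4 and myddosome pathway genes 12 were higher and 12 lower (camera adjusted p = 0.790), and 7 higher and 17 lower with library totals alone, which moved their median from -0.02 to -0.21 on the log2 scale. Cd14, the LPS co-receptor gene, was 3.09-fold higher in responders, Irak3 8.0-fold and Irak2 1.74-fold higher, and Myd88 (chromosome 9, 119335934 to 119340018) was 1.21-fold lower at 210 ± 6.32 against 255 ± 1.5 CPM. Irak4 was 1.14-fold lower (adjusted p = 0.000645), a call that was lost in the 10 libraries without neural transcripts at adjusted p = 0.0995, with a log2 fold of -0.12 in place of -0.19.

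The other lists had no call for responders against bystanders. Members higher and lower were 7 and 8 of 16 for inflammasome and lytic cell death (camera adjusted p = 0.352), where Nlrp3 was 3.64-fold higher and Ripk1 2.1-fold lower. They were 9 and 13 of 25 for resting macrophage identity (0.454), or 14 lower adjusted over the list alone, and 11 and 6 of 22 for immediate-early genes (0.173). They were 8 and 4 of 17 for p53 targets (0.115), where Gdf15, a stress-induced growth factor gene, was 6.97-fold higher. Lysosome and vacuolar ATPase genes were higher for 12 and lower for 16 of 31 (0.352), autophagy receptors and lipid droplet genes for 10 and 9 of 22 (0.458), glycolysis and hypoxia genes for 14 and 7 of 23 (0.105) and nuclear oxidative phosphorylation genes for 16 and 6 of 32 (0.347). Among markers of other cell types, neutrophil genes were higher for 2 of 3 (0.318), dendritic cell genes lower for 2 of 4 (0.152), lymphocyte genes higher for 1 and lower for 2 of 3 (0.221). The 5 fibroblast genes had no call (0.817), with adjusted p = 0.634 for Col1a1 and 0.781 for Col1a2 by edgeR. Clec10a, a lectin gene on the dendritic cell list that macrophages also express, stood at 239 ± 3.98 CPM in bystanders and 47.3 ± 2.42 CPM in responders. Col1a1 and Col1a2, collagen genes, ranged from 1.70 to 53.7 CPM and from 0 to 9.82 CPM across bystander libraries, with the highest values in replicate 3. With library totals alone lysosome genes were lower for 25 and higher for 4 (0.0185), immediate-early genes were called (0.0203) at 11 higher and 9 lower. The medians of p53, autophagy, glycolysis and oxidative phosphorylation genes then turned from 0.06 to -0.13, from 0.07 to -0.12, from 0.14 to -0.05 and from 0.06 to -0.13, with 6 and 8, 6 and 11, 7 and 12 and 2 and 26 members higher and lower, and resting macrophage identity had 7 and 16.

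In all, 4364 of 12589 genes were higher in responders and 4449 lower by edgeR's quasi-likelihood test, 733 and 671 of them by at least 2-fold. The share of calls that were higher was 49.5%, and 27.8% with library totals alone, which moved the median over all genes from -0.01 to -0.20 on the log2 scale. Small changes are therefore relative to the middle of the tested genes.

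LPS itself, in ungated cells, raised cytokine and interferon-stimulated genes most. Il1b rose 389-fold from 7.32 ± 1.24 CPM in untreated cells to 2825 ± 68.0 CPM in the pool, Il6 rose 505-fold to 752 ± 31.5 CPM, Nos2 290-fold and Tnf 24.9-fold. Cxcl10 rose 120-fold from 29.2 ± 1.38 to 3491 ± 63.2 CPM, with adjusted p = 4.56e-87. Csf3, Il1a and Il27 rose 268-fold to 476-fold. Serpina3f had 6, 7, 3 and 3 reads in untreated libraries and 984 to 1498 in pool libraries, and Ccl17 3, 3, 1 and 3 against 447 to 596. Lcn2 rose 388-fold, and 681-fold in the 6 libraries with neural transcripts, which hold a single untreated library with 8 reads of it. Cytip fell 4.72-fold, Tmem158 3.80-fold, St6gal1, a sialyltransferase gene, 3.68-fold and Cebpa, a myeloid transcription factor gene, 3.20-fold. Treml1, Asb4, Fam189a2, Angptl4, Dmpk and Il1rl1 fell 3.16-fold to 3.75-fold.

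All 46 interferon-stimulated genes rose at least 2-fold in the pool (camera adjusted p = 6.78e-35, and 0.000207 with an estimated correlation), as did 27 of 28 cytokines (28 higher, adjusted p = 2.54e-16). All 23 NF-kappaB feedback regulators (2.54e-16), all 26 effector genes (1.56e-15) and all 19 antigen presentation genes (1.56e-15) were higher. Inflammasome genes were higher for 11 and lower for 3 of 16 (0.000397), immediate-early genes for 15 and 2 of 22 (6.94e-05), or 16 higher adjusted over the list alone, and actin genes for 26 and 3 of 30 (3.97e-11). TLR4 pathway genes were higher for 19 and lower for 6 of 29 (0.00376): Cd14 rose 3.98-fold, Irak2 3.81-fold and Myd88 1.84-fold, while Tlr4 fell 1.62-fold from 51.9 ± 1.05 to 31.8 ± 2.19 CPM. With library totals alone the median of the TLR4 list was -0.11 in place of 0.22 on the log2 scale, with 10 members higher and 16 lower. All 28 G2/M genes (1.26e-13) and 27 of 28 G1/S genes (5.23e-10) were lower, and ribosome biogenesis genes were lower for 18 and higher for 2 of 24 (0.000745). Each of these calls held with an estimated correlation.

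Lists that moved less depended on the scaling. Heat shock genes were higher for 14 of 17 (camera adjusted p = 0.00234), NRF2 targets for 13 of 18 (0.00157) and ribosomal protein genes for 32 of 32 (3.10e-12), but with library totals alone their medians were -0.05, -0.07 and -0.02 on the log2 scale and the calls were lost. Autophagy, glycolysis and oxidative phosphorylation genes were higher for 13 of 22, 17 of 23 and 25 of 32 (0.0210, 0.000930 and 0.00404). With an estimated correlation these had adjusted p = 0.0714, 0.0522 and 0.183, and with library totals alone their medians were -0.18, -0.14 and -0.19. There was no call for resting macrophage identity (12 higher and 9 lower of 25), unfolded protein response (11 and 6 of 23, or 7 lower adjusted over the list alone), p53 targets (8 and 6 of 17), lysosome (17 and 10 of 31), mitochondrially encoded (1 and 8 of 13, or 2 higher adjusted over the list alone) or cholesterol genes (6 and 8 of 21). Library totals alone moved these counts to 9 and 15, 8 and 15, 6 and 10, 7 and 22, 0 and 10 and 1 and 17, in that order. The lists of neutrophil, dendritic cell (1 higher and 1 lower of 4, or 3 lower adjusted over the list alone), lymphocyte and fibroblast markers had none either. In all, 4292 genes rose and 4757 fell by edgeR, 1224 and 471 at least 2-fold. The share of calls that were higher was 47.4%, and 21.6% with library totals alone, which moved the median over all genes from -0.03 to -0.36.

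The genes that LPS regulated in the pool were then followed across the gates. Of the 1224 induced at least 2-fold, 856 were higher in responders than bystanders (501 at least 2-fold), 207 were lower and 161 did not pass, with a median of 0.77 on the log2 scale (bootstrap interval 0.71 to 0.84). Il1b, Il6 and Tnf are among the first group, and Irf1, Socs1 and Irgm2, an immunity-related GTPase gene, among the second. Of the 471 repressed, 366 were lower in responders, among them Kif11, Cytip and St6gal1, 17 were higher and 88 did not pass, with a median of -0.97. Against all genes tested, induced genes were enriched among those higher in responders (odds ratio 5.21, Fisher's exact test p = 4.79e-155), and repressed genes among those lower (odds ratio 6.86, p = 1.36e-81). Genes are not independent, so these p-values describe the overlap only. The overlap is also partly built in, although the comparisons share no library. The pool lay close to the responders, with 9 genes at least 2-fold higher and 38 lower in responders. Genes that LPS moved in the pool are therefore largely those it moved in responders.

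**Figure D2:**
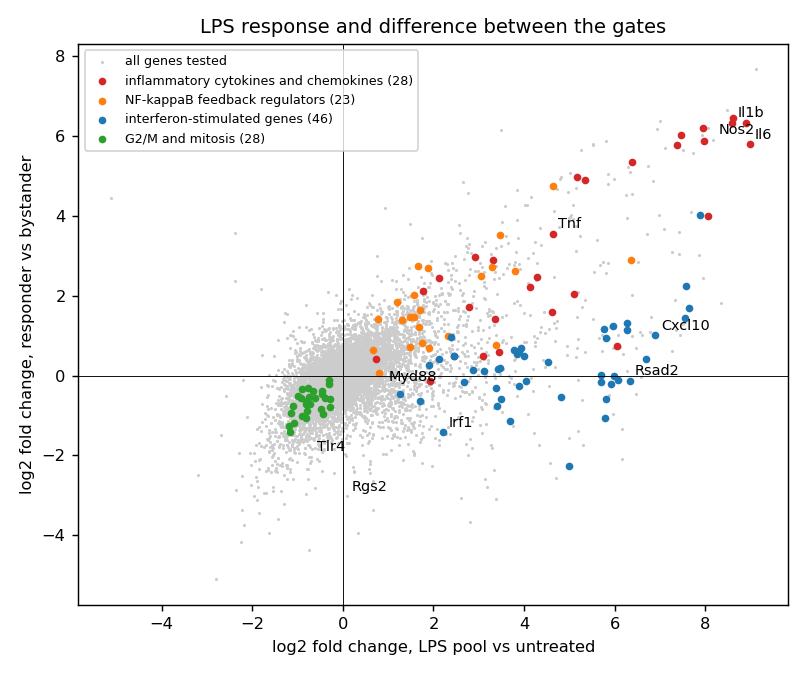
Each point is a gene, placed by its log2 fold change for LPS pool against untreated (horizontal axis) and for responder against bystander (vertical axis), with 4 lists coloured. Cytokines and NF-kappaB feedback regulators lie in the upper right, interferon-stimulated genes lie to the right on both sides of 0, and G2/M genes lie in the lower left.

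Set against untreated cells, responders and bystanders shared the interferon-stimulated genes and differed in the cytokines. All 46 interferon-stimulated genes were at least 2-fold higher in both gates, by medians of 4.22 in responders and 4.39 in bystanders on the log2 scale. In bystanders Cxcl10 was 67.6-fold higher than in untreated cells (adjusted p = 1.20e-84 by edgeR), Myd88 2.29-fold and Acod1 10.2-fold higher. Tnf was 2.41-fold higher in bystanders and 28.2-fold in responders. Il6 was 9.50-fold higher in bystanders, and 3.85-fold in the libraries without neural transcripts. Nos2 was 6.12-fold higher, and 2.87-fold in those libraries. Il1b was 5.56-fold higher in bystanders (adjusted p = 0.00371), and in the libraries without neural transcripts it was 1.11-fold higher at adjusted p = 0.208, so the call was lost. In responders the folds over untreated were 450 for Il1b, 529 for Il6 and 367 for Nos2.

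Cytokine genes had a median of 4.98 on the log2 scale in responders and 2.16 in bystanders against untreated, and 1.15 in bystanders without the neural-transcript libraries, where 16 of 28 were higher in place of 22. NF-kappaB feedback regulators had medians of 1.95 and 0.36, with 23 higher in responders and 16 higher and 5 lower in bystanders, or 12 and 5 with a bystander median of 0.16 with library totals alone. Effector genes had medians of 3.45 and 1.16, or 0.82 in bystanders without those libraries. G2/M genes were lower for 28 of 28 in responders, and lower for 21 and higher for 3 in bystanders, with medians of -0.97 and -0.27, the latter -0.46 with library totals alone. Tlr4 was 1.69-fold lower in responders than in untreated cells and 2.42-fold higher in bystanders. Nfkbia was 10.7-fold higher in responders and 1.62-fold in bystanders, and Tnfaip3 9.88-fold and 1.75-fold. Irak4 did not pass in bystanders (adjusted p = 0.133), but it was lower with library totals alone (8.25e-07), with upper-quartile factors (0.000550) and in the libraries without neural transcripts (0.0248). Il12b (0.608) and Ifnb1 (0.147) did not pass either, Ifnb1 having 0, 0, 2 and 0 reads in untreated libraries. Without untreated replicate 3, which holds those 2 reads, Ifnb1 passed at adjusted p = 0.0140.

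**Figure D3:**
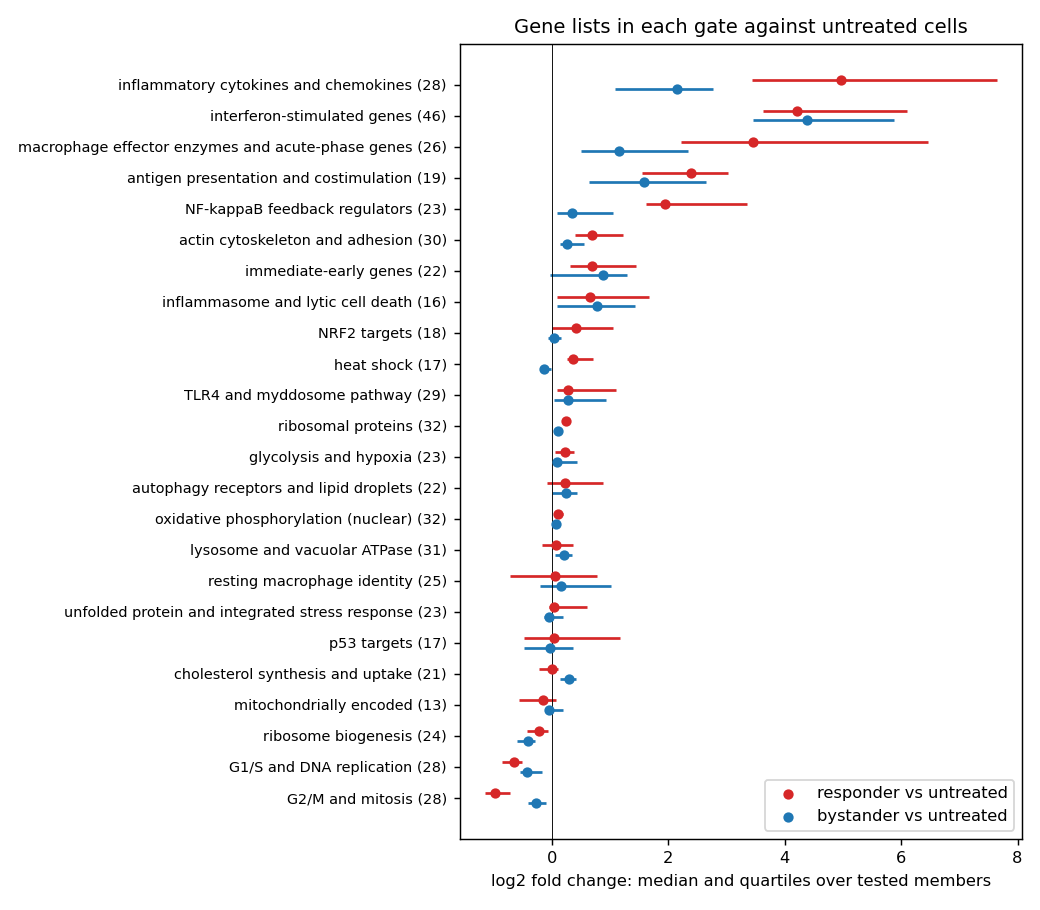
Median and quartiles of the log2 fold change over the tested members of each list (number in brackets), for responder and bystander libraries against untreated libraries. Cytokines, effector genes and NF-kappaB feedback regulators lie further right in responders, and interferon-stimulated genes have medians of 4.22 and 4.39.

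Against untreated, 4598 genes were higher and 4849 lower in responders (1357 and 785 at least 2-fold), and 4298 and 4147 in bystanders (946 and 370 at least 2-fold), by edgeR. The share of calls that were higher was 48.7% in responders and 50.9% in bystanders, and 21.7% and 27.5% with library totals alone, which moved the medians over all genes from -0.02 to -0.41 and from 0.01 to -0.18.

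The ungated pool lay close to the responders. Only 9 genes were at least 2-fold higher and 38 lower in responders than in the pool, although 2010 and 1195 passed edgeR's test. Tnf was 1.13-fold higher in responders, Cxcl10 1.14-fold, Cd14 1.16-fold and Irak2 1.24-fold, each past the test. Nfkbia was 1.09-fold higher (adjusted p = 0.00216), a call that was lost with library totals alone at adjusted p = 0.0927 and in the 6 libraries with neural transcripts at 0.141, with log2 folds of 0.07 and 0.10 in place of 0.12. Tlr4, Myd88, Il6, Il1b and Nos2 did not pass at adjusted p = 0.451, 0.232, 0.739, 0.620 and 0.0909. In that fit the spread of each gene is estimated over all 16 libraries, bystanders included. The libraries compared did not overlap for Il1b (3177 to 3334 CPM in responders, 2782 to 2926 CPM in the pool). Nor did they for Nos2 (1424 to 1482 CPM against 1082 to 1182 CPM). With only responder and pool libraries in the fit, Il1b was higher by 0.19 on the log2 scale (adjusted p = 1.23e-10) and Nos2 by 0.32 (1.57e-15). In the 10 libraries without neural transcripts Il1b was higher by 0.24 (1.85e-13), Il6 by 0.12 (4.27e-06) and Nos2 by 0.30 (1.34e-21), and 18 genes in place of 9 were at least 2-fold higher, against 1 with DESeq2. Of the calls 62.7% were higher in responders, and 30.6% with library totals alone.

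Bystanders differed from the pool at 4298 genes higher and 4142 lower by edgeR, 513 and 620 at least 2-fold. Tnf was 10.3-fold lower, Nfkbia 6.08-fold, Acod1 5.68-fold and Cxcl10 1.77-fold lower. Il1b was 70.0-fold lower over all libraries and 333-fold in those without neural transcripts, Il6 53.1-fold and 124-fold, and Nos2 47.4-fold and 107-fold. Tlr4 was 3.93-fold higher in bystanders, and Myd88 1.25-fold. Of the calls 50.9% were higher in bystanders, and 68.4% with library totals alone, which moved the median over all genes from 0.00 to 0.14.

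The mean of both gates, each weighted equally on the log2 scale, was also set against the pool, which was collected later. It was planned as a check of handling. The pool lay close to the responders, so this mean departs from it wherever the gates differ, and handling cannot be told apart. For inflammatory genes the gates lay on opposite sides of the pool: cytokine genes had a median of 0.18 on the log2 scale in responders and -2.77 in bystanders against it, NF-kappaB regulators 0.21 and -1.36, and effector genes 0.21 and -2.43. The lower mean of these lists therefore comes from bystanders. Antigen presentation (0.135 and -0.44), heat shock (0.104 and -0.414), NRF2 (0.136 and -0.325), actin (0.128 and -0.335) and G2/M genes (-0.20 and 0.441) also lay on opposite sides. Ribosome biogenesis (-0.043 and -0.23), ribosomal protein (-0.046 and -0.191), interferon-stimulated (0.197 and 0.123) and cholesterol genes (0.016 and 0.305) lay on the same side in both gates. In the mean of both gates, 26 of 28 cytokines were lower and 1 higher (camera adjusted p = 3.73e-21). Of 23 NF-kappaB regulators 21 were lower, and 1 higher when adjusted over the list alone (5.12e-21). Of 26 effector genes 23 were lower (2.13e-24). Antigen presentation genes were lower for 13 of 19 (6.64e-05), heat shock genes for 14 of 17 (1.39e-05), NRF2 targets for 9 of 18 (0.000362), or 10 adjusted over the list alone, actin genes for 20 of 30 (0.000137) and ribosome biogenesis genes for 20 of 24 (2.63e-06). Ribosomal protein genes were lower for 30 of 32 (1.54e-11), with adjusted p = 0.0737 with an estimated correlation. Interferon-stimulated genes were higher for 25 and lower for 17 of 46 (0.000863), with adjusted p = 0.164 with an estimated correlation. G2/M genes were higher for 18 of 28 (0.000686), or 19 adjusted over the list alone, and cholesterol genes for 13 of 21 (0.00143). The calls other than those of the ribosomal protein and interferon-stimulated lists held with an estimated correlation. The other 16 lists had no call by camera, except lysosome genes with library totals alone (0.0126), mitochondrially encoded genes in the libraries without neural transcripts (0.0213), and oxidative phosphorylation genes without LPS pool replicate 2 (0.0337) or 3 (0.0241), bystander replicate 1 (0.0458) or responder replicate 2 (0.0421).

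By gene, Irgm2 was 2.14-fold higher in the mean of the sorted groups, Tgtp2, a T-cell-specific GTPase gene with a near-identical copy, 2.11-fold, Xylt1 2.09-fold, Trim21 1.92-fold and Tasor2 1.90-fold. Cd3eap, Zfp395, Ankle1, Tacc2 and Kcnq1ot1 were 1.47-fold to 1.59-fold lower. Il1b was 7.78-fold lower in the mean of the sorted groups, and 16.8-fold in the libraries without neural transcripts, Nos2 6.12-fold and 9.29-fold. Tnf was 3.02-fold and Nfkbia 2.36-fold lower. Irak4 was higher by 0.12 on the log2 scale (adjusted p = 0.0210), a call that was lost with DESeq2 (0.0573), in the 6 libraries with neural transcripts (0.468) and without LPS pool replicates 1 (0.0803), 2 (0.122) or 4 (0.0529), with log2 folds of 0.11, 0.08, 0.11, 0.10 and 0.11 in that order. In all 3078 genes were higher and 3123 lower by edgeR, 62 and 176 at least 2-fold. Of the calls 49.6% were higher, and 61.5% with library totals alone.

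Besides macrophage transcripts, the 6 libraries named above held transcripts of 15 neural genes at 743 to 871 counts per library, against 20 to 42 in the other 10. Map1b, a microtubule-associated protein gene of neurons, averaged 8.27 against 0.18 CPM and Dcx, the doublecortin gene, 3.74 against 0.01 CPM. The set of libraries crosses the groups, with 2 of 4 libraries in the bystander and pool groups and 1 of 4 in the responder and untreated groups. The third principal component, with 7.6% of the variance, placed these 6 libraries at -25.5 to -14.3 and the other 10 at 6.25 to 17.7, with no overlap. Without these libraries 4028 genes were higher and 4026 lower in responders than bystanders.

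**Figure D4:**
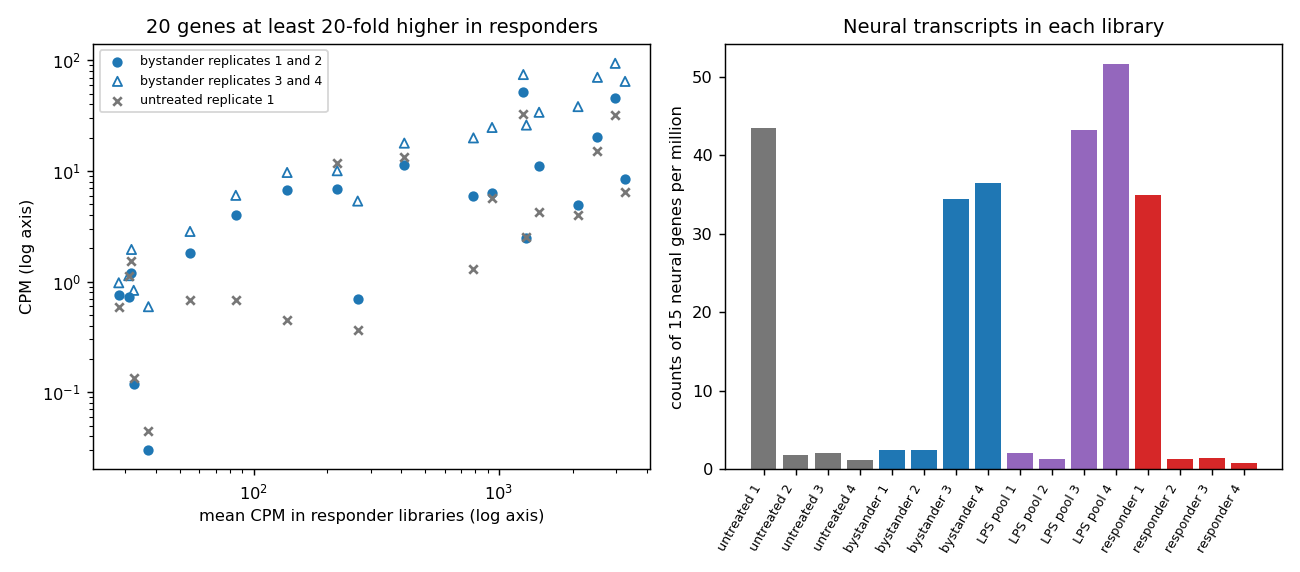
Left, level of 20 genes in bystander replicates 1 and 2, bystander replicates 3 and 4 and untreated replicate 1, against their level in responders, in CPM on log axes. Right, summed CPM of 15 neural genes in each library, with 6 libraries at 34.5 to 51.6 and the other 10 at 0.84 to 2.47.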

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

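The tests of responder transcripts in bystander replicates 3 and 4, of the neural transcripts and of the makeup of the LPS pool were chosen after those values were seen, as was the comparison of LPS-induced genes with the largest cell cycle change and the reading of mitochondrial shares against ungated libraries. The other tests were fixed before the data were examined.

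The difference between the gates in LPS-induced genes held for 1063 of 1224 of them. Unequal depth is argued against, since 96.2% of these calls (1023) were made again when responder and bystander libraries were thinned to equal totals. Cell cycle stage cannot be told apart from the gate: with the cell cycle score of each library as a covariate 1.4% of the calls (15) were kept, which is the outcome set in advance for this cause, but the score varied by at most 0.039 within groups and differed by -0.482 between the gates, so the covariate stands in for the gate. In a comparison chosen afterwards, 390 of the 1063 changes were larger than the largest of any cell cycle gene, 1.41 on the log2 scale for Mki67. This cannot decide the question either, since LPS-induced and cell cycle genes need not change by equal amounts. RNA quality also cannot be told apart: bystanders had 1.301 times the mitochondrial share of responders with no overlap, again the outcome set in advance for this cause, but untreated cells had 1.357 times the share of the LPS pool with no gate between them, so a biological difference in the response to LPS remains untested beside these.

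Bystander replicates 3 and 4 held more of the responder transcripts than replicates 1 and 2. Over 20 genes at 20 CPM or more in responders and at least 20-fold higher there than in replicates 1 and 2, the excess was 1.77% of the responder level (median), and its upper quartile was 1.25 times its lower one (1.59% to 1.99%), with single genes from 0.780% (Ccl22) to 2.52% (Upp1), consistent with responder cells or their RNA carried into these samples. A weak LPS response of these bystander cells that raised moderately changed genes by a larger share is argued against. The 278 genes 2-fold to 5-fold higher had a median share of 1.98% (bootstrap interval 1.47% to 2.35%), 1.115 times that of the first set. A weak response at the same share for every gene, or in a few bystander cells, would also give equal shares and cannot be told apart. Reads exchanged among the 6 libraries with neural transcripts cannot be told apart: untreated replicate 1 had a median excess of -0.028% of the responder level (-0.11% to 0.03%), but it is 1 library, and an exchange among some of the others would leave it clean. Cells cannot be separated from RNA here, and why these libraries also hold neural transcripts was not tested.

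Transcripts of 15 neural genes, which are outside the lists and named genes compared between groups, came to 34.49 CPM in the lowest of the 6 libraries, 13.95 times the highest of the other 10. The 6 libraries were set apart by this same value, so the ratio itself is no test of depth. Library totals argue against depth in the LPS pool, where replicates 3 and 4 had 17195052 and 15287344 counts. Replicates 1 and 2, without the transcripts, had 18627175 and 22655307. In bystanders the libraries with the transcripts had the higher totals. Of 30 further neural genes not looked at before, 24 had at least 10 reads in all, and 17 of these (70.8%) were higher in the libraries with the transcripts in all 4 groups, against 9.8% of 16476 genes with as many reads, among them Scn2a at 0.449 against 0.004 CPM and Gad1 at 0.342 against 0.005 CPM. The share depends on which genes are kept, a choice made after the outcomes were seen (14 of the 18 with a mean under 1 CPM over all libraries, or 77.8%, against a bound of 75%), so RNA or reads from a nervous system sample remain an open candidate explanation, and no such sample was used here nor the step at which they entered tested. The most abundant were Map1b at 8.27 CPM, Mapt at 3.86 CPM and Stmn2 at 3.74 CPM, and of the 15 Tubb3 also stood at 1.055 CPM in the libraries without. The labels name no gate that would remove neural cells other than side scatter, nor any batch, but the third principal component parts these libraries from the rest in all 4 groups, so a separate library or sequencing run may set them apart, and neither that nor a biological origin was tested.

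Each comparison was set against other splits of the same libraries into groups, which shows only whether libraries of a group resemble each other. The replicates may be technical, so the splits cannot exclude a chance difference between cultures or sorts. They also took no account of any pairing of same-numbered libraries, which the correlations cannot tell apart from the neural-transcript set. For each pair of groups the real split was the only 1 of 35 to call as many genes: 8847 against at most 0 in any other split for responder against bystander, 8803 against 0 for LPS pool against untreated, 9460 against 0 for responder against untreated and 8478 against 0 for bystander against untreated. The values were 3043 against 2 for responder against LPS pool and 8205 against 42 for bystander against LPS pool. For the mean of the sorted groups against the pool, 2 of 100 drawn splits called as many as the real 6167, and the other, with 8567, put all 4 bystander libraries in place of the pool, which points to a structure of the samples, the bystander group standing apart.

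Among groups of 4 libraries, 24 of 417 values stood far from the other 3 by Dixon's ratio, where chance gives about 1 in 20, or 20.9; 12 of the 24 were in libraries with neural transcripts. Among collagen genes, Col1a1 was 73.6 CPM in LPS pool replicate 3 against 1.85 to 5.54 CPM in the others (ratio 0.948) and 53.7 CPM in bystander replicate 3 against 1.70 to 4.92 CPM (0.938), and Col1a2 gave ratios of 0.912 and 0.895 in the same libraries. Col1a1 also went with the replicate number in the other groups. Replicates 1 to 4 held 14.1, 4.89, 18.2 and 6.72 CPM in responders and 12.4, 4.45, 17.6 and 6.22 CPM in untreated libraries. Most of these responder and untreated libraries are without neural transcripts, and the cause was not tested. In the LPS pool, replicate 3 also stood apart for Gdf15 (0.932), Rgs2 (0.922) and Tnf (0.904), replicate 4 for Ccl5 (0.869), Il1b (0.892) and Nos2 (0.854), replicate 1 for Cd4 (0.856) and Cebpa (0.901) and replicate 2 for Mmp8 (0.866). In untreated libraries, replicate 2 stood apart for Hspa8 (0.848) and Il1rn (0.935) and replicate 3 for Msr1 (0.951) and St6gal1 (0.906). In responders, replicate 1 stood apart for Il1rn (0.863), replicate 2 for Nfkbia (0.875) and Saa3 (0.932) and replicate 3 for Nop56 (0.905). In bystanders it was replicate 1 for Rrm1 (0.888) and Tlr4 (0.928) and replicate 4 for Tgtp2 (0.863). For Tlr4 the values were 128 CPM in bystander replicate 1 and 125 CPM in the others.

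Named genes moved in opposite directions in the gates against untreated, and responder against bystander tests that difference itself, with the log2 values given here. Lower in responders and higher in bystanders than untreated were Tcp11l2 (-2.895), Il18rap (-2.58), Enc1 (-2.429), Clec10a (-2.339), Tlr4 (-2.029), Atp6v0d2 (-1.591), Cd4 (-1.359), Il7r (-1.167), Xylt1 (-1.16) and Ripk1 (-1.071). Cd4 rested on few reads, at 8 to 23 in responder, 19 to 28 in untreated and 26 to 46 in bystander libraries. Its adjusted p against untreated was 0.0457 in responders and 0.0187 in bystanders by edgeR. Higher in responders and lower in bystanders were Irak3 (3.0), Gdf15 (2.802), Tnip1 (2.687), Slc3a2 (0.991), Hsph1 (0.873), Hspa8 (0.831), Kcnq1ot1 (0.796) and Rrp9 (0.719). With library totals alone Hsph1, Kcnq1ot1 and Rrp9 were no longer higher in responders than untreated, at -0.01, -0.08 and -0.16.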

How the results depend on the processing

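The fits by neural-transcript set and the block fits of 2 groups alone were chosen after the data were seen; the others were fixed before. Of 207 gene results 186 kept their direction and call under every setting tried for them (33 settings in all), and of 84 list results 40 did. The cause of each change below was not tested unless said. Depth limits Il12b and Ifnb1, which rest on few reads. The collagen genes vary widely between libraries of 1 group, with Col1a1 going with the replicate number as given above.

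With library totals alone, genes higher and lower were 2580 and 6695 for responder against bystander, 2216 and 8027 for LPS pool against untreated (1307 at least 2-fold lower), 2286 and 8238 for responder against untreated (1880), 2491 and 6576 for bystander against untreated (642) and 1073 and 2438 for responder against LPS pool, and 2755 were lower for bystander against LPS pool. This follows from leaving out the composition factors, which moves all genes of a library alike. Upper-quartile factors also moved the share of calls that were higher. Against untreated it fell from 47.4% to 36.7% for the LPS pool, from 48.7% to 36.8% for responders and from 50.9% to 37% for bystanders. For responder against LPS pool it fell from 62.7% to 48.4%. The share moved less for responder against bystander (45.9%), bystander against LPS pool (51.8%) and the mean of the sorted groups (47.5%). For responder against LPS pool, genes at least 2-fold higher were 1 with DESeq2, 25 without a low-count filter, 4 with the stricter filter and 18 without the neural-transcript libraries, and lower 25 with DESeq2, 82 without a filter and 22 with only those libraries. In the latter 662 were higher and 205 lower, with fewer samples. For the mean of the sorted groups against the pool, 305 were at least 2-fold lower without a filter, 40 at least 2-fold higher with the stricter filter, and 2035 higher and 1980 lower with only the neural-transcript libraries.

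The median log2 fold of LPS-induced genes was 0.814 with upper-quartile factors, 0.816 without the neural-transcript libraries, 1.102 for a 4-fold set and 0.252 with no fold threshold, and 0.751 to 0.818 when each replicate was left out. That of LPS-repressed genes was -0.865 with upper-quartile factors, -0.846 with library totals alone, -0.896 without a filter, -1.013 with only the compared groups, -0.928 without the neural-transcript libraries, -2.096 for a 4-fold set and -0.244 with no threshold, and -0.987 to -0.941 when each replicate was left out.

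Of named genes, those that changed sign did not pass in either setting unless given. Without the neural-transcript libraries the log2 fold was 0.00446 for Cebpe, 1.56 for Col1a1 and 1.71 for Col1a2 (responder against bystander), -0.0439 for Ifnb1 (bystander against untreated), and -0.00900 for Myd88 and 0.151 for Ifnb1 (responder against LPS pool). Without responder replicate 2 Cebpe passed for responder against bystander, at -0.51 (adjusted p = 0.0488) in place of -0.20 (0.422). With only those libraries, where the lone responder and untreated libraries are assumed to vary like the other groups, it was 0.0443 for Irak4 and -0.981 for Il12b (bystander against untreated), and -0.0514 for Irak4, -0.0169 for Il6 and -0.949 for Il12b (responder against LPS pool). With the set as a covariate it was 0.104 for Col1a1 and 0.321 for Col1a2. For responder against LPS pool it was -0.0139 for Myd88 and -0.0275 for Irak4 with library totals alone. When each replicate was left out, it ran from -1.035 to 1.752 for Col1a1 and from -0.818 to 2.287 for Col1a2 (lowest without bystander replicate 4, highest without 3), from -0.313 without bystander replicate 3 to 3.836 without untreated replicate 3 for Ifnb1 (bystander against untreated), and from -0.30 without responder replicate 3 to 0.00121 without LPS pool replicate 3 for Ifnb1 (responder against LPS pool).

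By fry, which tests whether the genes of a list move one way and not whether they differ from other genes, 20 lists were higher for responder against bystander (10 by camera), 5 lower for LPS pool against untreated (3), and 7 higher and 17 lower for the mean of the sorted groups (3 and 9). Resting macrophage identity, without a call by camera, was called in the opposite direction, at adjusted p = 4.69e-05 for responder against bystander and 0.0011 for the sorted groups. With library totals alone 9 lists were higher for LPS pool against untreated (15), and ribosomal proteins for responder against bystander (0.823) and glycolysis (0.926) and oxidative phosphorylation (0.185) for LPS pool against untreated changed direction without a call.

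Over all 4 groups, 12 of 24 pairs with the same number had a correlation of deviations over 0.1 (range -0.468 to 0.605), and 10 of 16 libraries correlated best with their own number. All 4 pairs had a correlation over 0.1 for LPS pool with bystander and for responder with untreated libraries. The numbers there also follow the neural-transcript set and, as given above, the level of Col1a1. In fits of those groups alone with the replicate block, 4694 genes were higher and 4765 lower for responder against untreated and 4167 and 4043 for bystander against LPS pool, and no named gene changed its call. With the replicate block in all 16 libraries 4356 genes were higher and 4451 lower for responder against bystander, 4292 and 4751 for LPS pool against untreated, 4597 and 4842 for responder against untreated, 4292 and 4149 for bystander against untreated, 2004 and 1190 for responder against LPS pool, 4277 and 4109 for bystander against LPS pool and 3084 and 3106 for the mean of the sorted groups. Col1a2 (responder against bystander) changed sign in it, to 0.313, and no other named gene or list changed its call.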

Other observations

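The genes in the first paragraph were chosen after their values were seen, and the test of the makeup of the LPS pool was chosen after the result was seen.

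Of the genes that moved apart in the gates against untreated cells, 15 did so by at least 2-fold each way, all also tested between the gates by edgeR. P2ry2, a receptor gene for extracellular nucleotides, stood at 65.5 ± 0.884 CPM in responders, 23.4 ± 1.17 in untreated cells and 11.3 ± 0.428 in bystanders (SD, n = 4 each; adjusted p = 5.41e-47 for responder against bystander by edgeR). In the other direction Il18rap, a subunit gene of the interleukin-18 receptor, stood at 6.77 ± 0.61, 16.5 ± 0.696 and 40.5 ± 0.674 CPM in that order (adjusted p = 1.42e-41) and Glcci1 at 4.11 ± 0.696, 8.54 ± 1.21 and 20.9 ± 0.727 CPM (adjusted p = 3.64e-31). In all 1149 genes passed in opposite directions, and 988 with library totals alone, of which 388 were shared.

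Members of 3 further lists were counted in the gates against untreated cells, with no list test. In bystanders lysosome and vacuolar ATPase genes were higher for 23 and lower for 3 of 31, with a median of 0.21 on the log2 scale, and cholesterol genes higher for 15 and lower for 3 of 21, with a median of 0.30. With library totals alone the lysosome counts were 13 and 11 with a median of 0.02, and the cholesterol counts 13 and 5 with a median of 0.10. In responders lysosome genes were higher for 17 and lower for 10, with a median of 0.08, and cholesterol genes for 6 and 8, with a median of 0.005. Library totals alone gave 7 and 21 (median -0.30) and 1 and 18 (median -0.38) in responders. Heat shock genes were lower for 10 and higher for 2 of 17 in bystanders, by a median of -0.12, and higher for 14 in responders, by a median of 0.37. Library totals alone gave 14 lower with a median of -0.32 in bystanders, and 5 higher and 5 lower with a median of -0.01 in responders. Il1rn, the interleukin-1 receptor antagonist gene, was higher in both gates than in untreated cells (301 ± 4.35 CPM), at 6208 ± 58.0 CPM in responders and 1323 ± 28.8 CPM in bystanders. Ier3, an immediate-early gene, was 827 ± 16.4 CPM in responders, 97.8 ± 6.1 in bystanders and 103 ± 1.25 in untreated cells, the bystander difference having adjusted p = 0.0579 by edgeR. Bystander replicates 1 and 2 held Ier3 at 93.6 and 92.0 CPM, and replicates 3 and 4 at 101 and 105 CPM. With library totals alone the bystander log2 fold of Ier3 against untreated was -0.255. The scavenger receptor gene Msr1 was higher in both gates (513 ± 6.68, 141 ± 3.17 and 69.5 ± 1.58 CPM), and Atp6v0d2, a vacuolar ATPase subunit gene, stood at 36.8 ± 1.94, 111 ± 3.17 and 73.3 ± 1.65 CPM in that order.

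A hypothesis was that the LPS pool is a mixture of cells like those of both gates. On library totals alone, where a mixture of RNA is linear, the share of responder-like RNA that the pool levels would need was 0.878 (bootstrap interval 0.863 to 0.894) from 118 genes higher in responders and 0.952 (0.903 to 0.969) from 33 genes higher in bystanders. The difference of -0.074 lies between the bounds set for and against a mixture, so the hypothesis stays open. On TMM-scaled levels, where a mixture is not linear, the difference was -0.123, past the bound set against a mixture. The intervals there did not overlap (0.826 to 0.859 from genes higher in responders, 0.903 to 0.979 from genes higher in bystanders). On those levels 8 genes higher in bystanders had pool levels at or under the responder mean. Cells with side scatter between the gates, which the pool may hold, were not sampled here.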
